A study of Homo sapiens with 4 samples.

How the data were processed

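RNA from RKO colorectal cancer cells was measured in 4 libraries, an input and an SRSF1 immunoprecipitation (IP) library from wild type cells and the same from ZCCHC7-overexpressing (ZCCHC7-OE) cells, 1 library per group by the submitters' labels. Per the labels' protocols, SRSF1-bound RNA was recovered on antibody-coated beads, and the same text also describes an anti-m6A step on fragmented RNA, so the protocol does not settle which of the antibodies acted on which library. Libraries were made with random hexamers and selected for short inserts, per the labels' protocols. The submitters' processing notes name FastQC 0.11.5 and HOMER. The aligner and the splicing program were not given in the sources used here.

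Peaks were called by the authors with MACS 2.1.0.20150420, per the file headers, separately for each genotype with the IP library as treatment and the input as control. The caller used a p-value threshold of 0.005, an effective genome of 209714707 bp, no fragment model, fragments extended to 147 bp in wild type and 154 bp in ZCCHC7-OE, and all duplicate tags, per the file headers. The larger library was scaled to the smaller, per the file headers. The lists were tied to the genotypes through the initials in the library names that the headers give, RW for wild type and RO for ZCCHC7-OE. The deposited pileup is a signal, the number of extended IP fragments over a summit at the input's depth. The deposited fold is the ratio of the pileup plus 1 to the local input background plus 1. The deposited significance columns hold -log10 of the p-value and of the q-value. In the authors' splicing tables the p-value and false discovery rate are the authors' own, and the deposited inclusion level difference is a score from -1 to 1. Junction counts in the deposited tables are whole numbers for 2 libraries per side, in an order that is not stated, so no library was assigned to them.

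From these values the following was computed with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. Summits of 1 region were counted as 1 peak. Pileups multiplied by IP tags over input tags gave whole IP tags within 0.1 at 285 of 285 wild type and 238 of 238 ZCCHC7-OE summits, and these tags were divided by the IP total to give tags per 1000000. Recomputed Poisson p-values matched the deposited -log10 values within 0.05 at 164 of 165 wild type and 129 of 129 ZCCHC7-OE summits at the genome-wide background. That background was 0.0998 tags per position in wild type and 0.0716 in ZCCHC7-OE, and a call at that background took at least 8 IP tags in either list. Shares have 95% exact binomial (Clopper-Pearson) intervals, tag counts exact Poisson intervals, and ratios of tags the exact conditional binomial interval. Sequenced tags without molecular identifiers are not independent molecules, so all intervals cover counting error only. The authors' fold ranks and describes peaks within a list and is not compared between lists.

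Peaks were placed on the gene annotation deposited with the series, of 58735 genes. Its build is not stated in its header. Of its 18676 protein-coding genes with a symbol in the RefSeq table of GRCh38.p14, 18672 overlapped the position there (99.98%), so coordinates are given as in the files and correspond to GRCh38. The feature was taken at the peak midpoint in the order coding sequence, 3′ UTR, 5′ UTR, other exon, intron, intergenic, and genes at the summit of highest fold. Overlapping genes cannot be told apart because the lists have no strand. Peaks of the 2 lists overlapping by 1 bp were called shared, and 10000 random placements in genes or exons give the overlap by chance.

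Splicing events were taken from the authors' comparison at a false discovery rate of 0.05. Fixed before the data were examined was also Fisher's exact test of 1 library against 1, with Benjamini-Hochberg adjustment within the event type. Because the order of the libraries is not stated, it was run by position, taking a position to hold the same kind of library on both sides, for events with counts on both sides there. A form with the counts of a side's 2 libraries added was chosen after the counts were seen and was run before the form by position. Tested on simulated data at the real counts of the 46 events, the form with added counts called 0.0652% of events with no difference, 2.93% of events with an inclusion difference of 0.5 and 28.3% of those with a difference of 1. With 10 times the counts it called 79.2% of events with a difference of 0.5.

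Genes were named by a rule written before the data were examined: the 10 peaks of highest fold per list, the 10 shared peaks of highest mean rank, members of 14 fixed gene groups that had a peak (at most 4 per group) or an event, significant events or the deepest events with 20 junction counts in each library, and ZCCHC7 and SRSF1. Other genes are said to have been chosen after their values were seen. Alternatives tried were a higher fold or -log10 p for peaks, other overlap rules, other feature and gene assignment, other splicing thresholds, Fisher's exact test and inclusion levels without length correction. Counts of SRSF1 and m6A motifs were planned and not run, because no genome sequence was used here. The values of 1 gene are not reported here, and tests on named genes were run without it.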

Results

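RNA recovered with an antibody to the splicing factor SRSF1 was sequenced from RKO cells, a human colorectal cancer line, either wild type or overexpressing ZCCHC7. SRSF1 is an SR protein that recognises purine-rich exonic sequences, and ZCCHC7 is a zinc-knuckle subunit of the TRAMP complex, which hands nuclear RNA to the exosome. Each genotype had 1 library of RNA recovered with the SRSF1 antibody (IP) and 1 library of input RNA, 4 libraries in all. The protocol in the labels names the SRSF1 antibody but also describes an anti-m6A step, and the library names say only IP. The RNA is therefore called SRSF1-recovered only as far as that protocol goes. The peak lists were tied to the genotypes through the initials in their headers. With 1 library per group no difference below has a replicate check, and every interval covers counting error only. The wild type IP library held 1070075 tags and its input 142404. The ZCCHC7-overexpressing (ZCCHC7-OE) IP library held 690876 tags and its input 97545. The comparisons ask where SRSF1-recovered RNA lay in each genotype, whether the positions differed, and whether splicing differed between the genotypes.

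In wild type cells the strongest SRSF1 peak lay in an intron of PVT1, the long non-coding RNA next to MYC, at chromosome 8, 127897403 to 127898212. The authors' fold enrichment over input was 70.7 there, from 1055 IP tags, or 986 per 1000000 IP tags (95% interval 927 to 1047). An intronic peak in the long non-coding RNA LINC01812 followed at fold 63.5. Next came the 5′ UTR of EEF1A1, the translation elongation factor, at fold 54.1, and an intron of LRRC75A, which overlaps LRRC75A-AS1, at fold 42.3. The remaining top 10 peaks were an intergenic site on chromosome 4 at 176479539 (fold 36.9), the first coding exon of the ubiquitin-conjugating enzyme gene UBE2Q1 (31.7), ANKDD1A (25.8), a site at the 3′ end of GH1 (24.5), AC009120.2 (20.1) and a pericentromeric site on chromosome 1 at 125180029 (18.5). Of the 534 bp of the GH1 peak, 428 bp lay beyond the gene, and its summit lay in an annotated intron of CSHL1, a related gene. In ZCCHC7-OE 455 of 633 bp lay beyond GH1, and reads from these genes may not be separable.

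The wild type list held 229 peak regions with 285 summits. Regions had a median length of 210.0 bp and a median fold of 4.04. The top summit of a region held from 8 to 10985 IP tags, with a median of 38.0. At 143 regions (62.4%, 95% exact binomial interval 55.8 to 68.7) the input background was the genome-wide floor, so that no input tag lay at the summit or in the 1 kb around it. The authors' q-value passed 0.05 at 102 of the 229 regions.

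In ZCCHC7-OE cells the leading peaks lay at LRRC75A (fold 58.3), UBE2Q1 (47.4), the PVT1 intron (44.1), an intergenic site on chromosome 3 at 93470345 (41.8), EEF1A1 (40.2) and LINC01812 (35.7). HBB followed at fold 33.9, with a peak at chromosome 11, 5225575 to 5226153, that covered parts of intron 2 and exon 3. The 3′ end of GH1 (33.1), the chromosome 1 pericentromeric site at 125179876 (33.1) and the chromosome 4 site (25.6) completed the top 10. The list held 194 regions with 238 summits, a median length of 227.0 bp and a median fold of 4.62. The input background was at the genome-wide floor at 115 regions (59.3%, 52.0 to 66.3), and 101 regions passed a q-value of 0.05.

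The positions of SRSF1-recovered RNA were largely common to both genotypes. Of the 194 ZCCHC7-OE peaks, 142 (73.2%, 66.4 to 79.3) overlapped a wild type peak by at least 1 bp, and 142 of the 229 wild type peaks (62.0%, 55.4 to 68.3) overlapped a ZCCHC7-OE peak. The shared set included PVT1, LRRC75A, UBE2Q1, LINC01812, EEF1A1, GH1 and HBB, which with 3 intergenic sites had the highest mean ranks in the lists. There were 87 peaks in the wild type list alone and 52 in the ZCCHC7-OE list alone. Because peaks were called separately in libraries of different depth, a peak in 1 list alone is not shown to differ.

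Among 110 shared loci with a single summit in each list, the summits lay a median of 6.0 bp apart, and 101 pairs lay within 20 bp. Of 130 ZCCHC7-OE peaks in gene bodies, 92 overlapped a wild type peak, against a median of 1 and a maximum of 6 in 10000 random placements within the genes of the wild type list. Of 82 exonic peaks, 55 overlapped, against a median of 18 and a maximum of 30 when placed at random in exons of their own genes. At the gene level, 119 genes held a wild type summit and 112 a ZCCHC7-OE summit. The genes in common numbered 84, of which 55 were protein-coding.

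At the 140 merged loci with a peak in both lists, IP tags per 1000000 had a median log2 ratio of ZCCHC7-OE to wild type of 0.38. The interval of the ratio lay above 1 at 56 loci and below 1 at 6. At each locus the summit with the most tags in each library was used. Across loci, which are not independent replicates, log2 tags per 1000000 correlated with Pearson r of 0.923 and Spearman rho of 0.889. Relative to the median shift, 33 loci had intervals above it and 18 below it. Loci named in the rest of this paragraph other than HBB, GH1, UBE2Q1 and MT-RNR2 were chosen after their values were seen. The highest ratios were at an intergenic site on chromosome 12 at 66057546, 1.91 above the shift on the log2 scale (1.46 to 2.39), and in an intron of ZNF429, 1.76 above (1.28 to 2.27). Of the 6 loci in AVEN, a caspase inhibitor gene, 5 had intervals above the shift, led by the first exon, which CHRM5 overlaps, with 251 ZCCHC7-OE against 100 wild type tags, 1.58 above (1.24 to 1.93). HMGN5, a nucleosome-binding protein gene, lay 1.27 above (0.82 to 1.75), HBB 0.82 above (0.54 to 1.11), GH1 0.81 above (0.55 to 1.07) and the top UBE2Q1 locus 0.77 above (0.56 to 0.99). The peaks of AVEN and UBE2Q1 took up nearly all of their coding sequence, and whether copies of cloned coding sequence contributed to them was not tested. Below the shift lay ATAD2 (-1.27, -1.78 to -0.79) and UPF2, a nonsense-mediated decay factor (-0.89, -1.19 to -0.60). These ratios use IP tags alone, and the caller's local input background, recovered from the deposited fold and pileup, moved differently between loci. Its lowest possible value is the genome-wide floor, 0.0998 in wild type and 0.0716 in ZCCHC7-OE. It is given at each input's own depth, 142404 tags in wild type and 97545 in ZCCHC7-OE. Equal values are therefore not equal per 1000000 input tags. From wild type to ZCCHC7-OE the background went from 0.100 to 7.00 at ZNF429, 0.999 to 3.00 at HMGN5 and 0.147 to 0.308 at GH1. At the chromosome 12 site it was 1.999 and then 2.000, and at the top UBE2Q1 locus 0.294 and 0.308. It went from 2 to 1 at the first AVEN exon, 0.294 to 0.0717 at HBB, 2.000 to 0.462 at UPF2 and 0.9995 to 0.0720 at ATAD2. With so few input tags, a change in IP tags at a locus is not shown to be a change in enrichment. The MT-RNR2 site held the most tags in both libraries, 10266 per 1000000 in wild type and 9953 in ZCCHC7-OE. The 33 and 18 loci describe these libraries, not the genotypes.

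**Figure D1:**
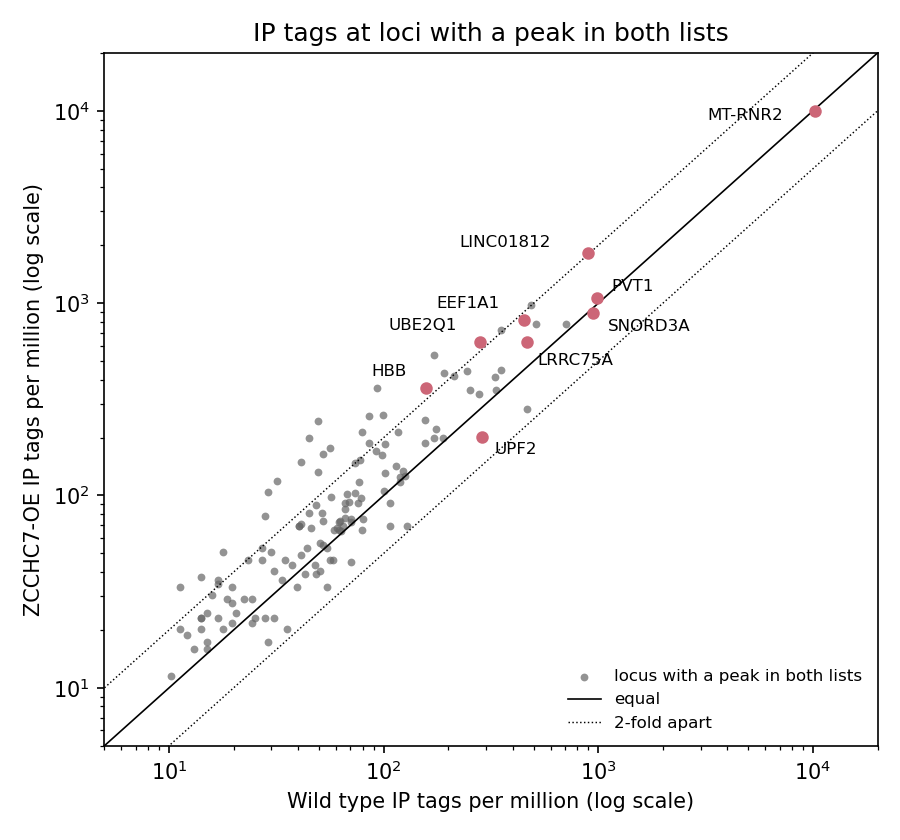
Each point is 1 of the 140 loci with a peak in both lists; both axes give IP tags per 1000000 on a log scale, wild type across and ZCCHC7-OE up, with lines at equality and at 2-fold. The median lies 0.38 above equality on the log2 scale, 114 points lie within 2-fold, and named loci are in red.

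Among the gene groups fixed before the data were examined, small structured RNAs, the largest group, had peaks in few of their members. The small nuclear RNA genes RNU11, RNU4ATAC and RNU6ATAC, components of the minor spliceosome that removes a rare class of introns, had a peak in both lists. So did the small nucleolar RNA SNORD3A (U3) and the U1-like copy RNU1-88P. SNORD3C held a peak in wild type alone and RNU1-11P in ZCCHC7-OE alone, and such genes have near-identical copies, so their tags are uncertain. In all, 6 of the 2260 genes of this group had a peak in each list, 5 of them in both. RNU11 had 521 tags in wild type (487 per 1000000) and 680 in ZCCHC7-OE (984 per 1000000), RNU6ATAC 82 and 81 tags, RNU4ATAC 32 and 35, and SNORD3A 1010 and 617. RNU11 overlaps AL360012.1 and the lists give no strand. At most 4 members were to be named per group, and naming all 7 here was decided after their values were seen. MALAT1 and NEAT1 had no peak.

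Protein-coding members of the other groups were sparse. MYC, the growth regulator, had 2 coding peaks in each list. The one of higher fold started at chromosome 8, 127740368 in wild type (fold 17.2) and at 127738596 in ZCCHC7-OE (23.9). EEF1A1 was the 1 translation factor of 12 with a peak, and HBB the 1 fibroblast or blood marker of 11. Of the 37 mitochondrial genes, MT-RNR2 had a summit in both lists. A single shared region from position 7664 to 11474 held 12 summits in wild type and 13 in ZCCHC7-OE. The summit of highest fold lay in MT-ATP8 in wild type, with 227 tags per 1000000, and in MT-CO3 in ZCCHC7-OE, with 269. At the summits of most tags the counts were 499 and 195, so the direction of the ratio depended on the summit. No peak lay in any of the 16 SR protein genes, SRSF1 included, the 20 hnRNP genes, or the 19 TRAMP and nuclear exosome genes, ZCCHC7 included. The same held for the 18 known SRSF1 splicing targets, 86 ribosomal protein genes, 109 histone genes, 11 cytoskeletal and glycolytic genes, 14 m6A machinery genes and 8 colon epithelium markers. A gene without a peak is one without enrichment over input detectable at this depth, not one without bound RNA.

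By gene feature, peaks in both genotypes fell in coding sequence, introns and intergenic sequence and almost never in 3′ UTRs. The midpoint lay in coding sequence for 73 wild type peaks (31.9%, 25.9 to 38.3) and 63 ZCCHC7-OE peaks (32.5%, 25.9 to 39.6). It lay in a 3′ UTR for 1 peak in each list (0.44% of wild type peaks, 0.52% of ZCCHC7-OE peaks), MAPKAPK5 in wild type and GLMP, which overlaps TMEM79, in ZCCHC7-OE, named after their values were seen. The 5′ UTR held 3 and 4 peaks, other exons 18 and 14, introns 51 (22.3%, 17.1 to 28.2) and 48 (24.7%, 18.8 to 31.4), and intergenic sequence 83 (36.2%, 30.0 to 42.8) and 64 (33.0%, 26.4 to 40.1). Each share in one genotype lay within the interval of the other. The intervals treat peaks as independent, but a few genes with many peaks, named after their values were seen, held much of the coding share. Of the 73 wild type coding peaks, 12 lay in CBL, 6 each in AVEN and UBE2Q1, 5 each in PLA2G4A and PSMB1 and 3 in CAPN2. Of the 63 in ZCCHC7-OE, 11 lay in CAPN2, 6 each in AVEN and UBE2Q1 and 2 in PSMB1.

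**Figure D2:**
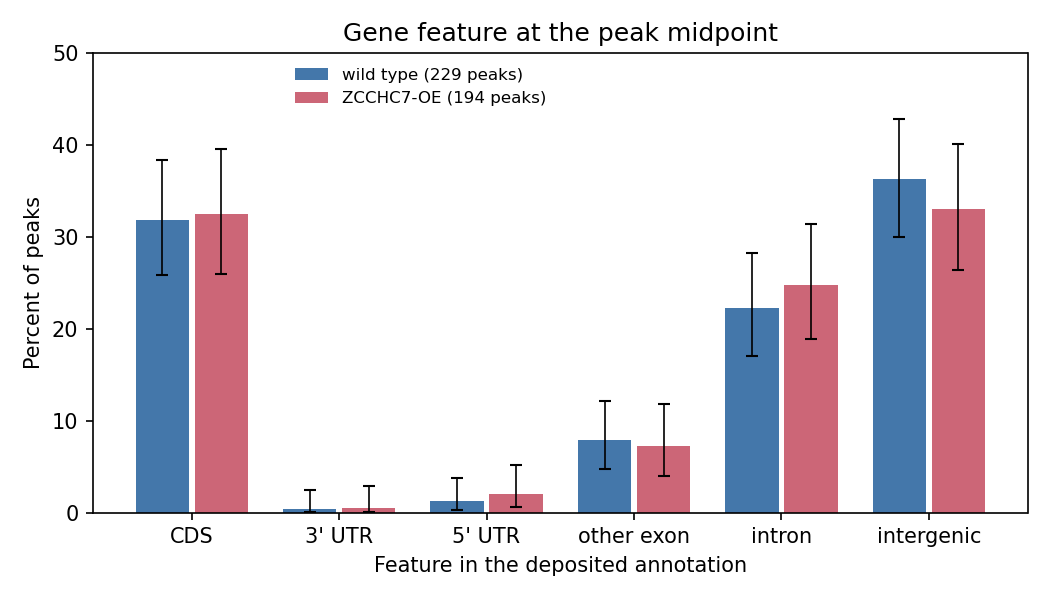
Bars give the percent of the 229 wild type and 194 ZCCHC7-OE peaks whose midpoint lies in each annotated feature, with 95% exact binomial intervals as error bars. Coding sequence, intron and intergenic shares are of similar height in both genotypes, and each 3′ UTR bar stands for 1 peak.

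Some protein-coding genes carried peaks on many of their exons, and some of these genes, named after their values were seen, had different numbers of peaks in the lists. CBL, the ubiquitin ligase gene on chromosome 11, had 12 wild type peaks over 13 of its 16 exons, with 11 to 42 tags each, and none in ZCCHC7-OE. The authors' q-value passed 0.05 at 3 of these 12 peaks. PLA2G4A, a cytosolic phospholipase gene, had 5 wild type peaks, none of which passed that q-value, and again none in ZCCHC7-OE. CAPN2, a calpain gene, ran the other way, with 4 wild type peaks and 13 in ZCCHC7-OE. PSMB1, a proteasome subunit gene, had 5 and 2. Some CAPN2 peaks in each list and all wild type PSMB1 peaks fell short of that q-value. UBE2Q1 had 7 peaks in each list and AVEN 6 in each, on all 6 of its exons. Peaks in CBL took up 80.9% of the coding sequence and no base of the 8368 bp 3′ UTR. In UBE2Q1, peaks took up 93.8% of the coding sequence in wild type and 97.7% in ZCCHC7-OE, and no base of the 1861 bp 3′ UTR.

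**Figure D3:**
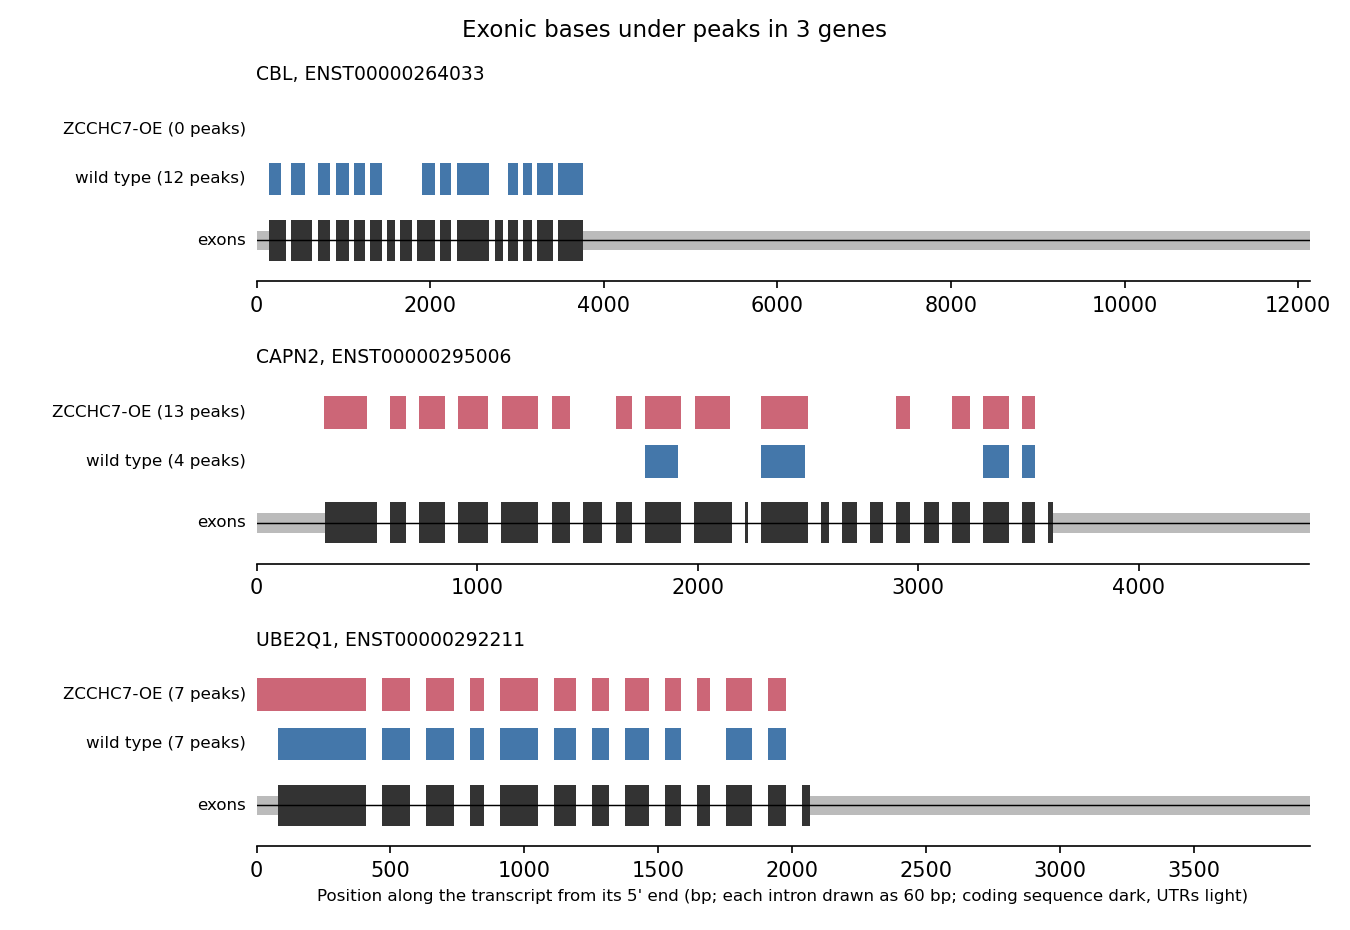
Exons of CBL, CAPN2 and UBE2Q1 are drawn from the 5′ end in bp, each intron shortened to a fixed gap, with coding sequence dark, UTRs light, and the exonic bases under wild type (blue) and ZCCHC7-OE (red) peaks above. Peak bases in introns are not drawn. Peaks cover coding exons and leave the 3′ UTRs bare, with 12 wild type and 0 ZCCHC7-OE peaks in CBL and 4 and 13 in CAPN2.

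No splicing event passed the authors' threshold between the genotypes. The authors' deposited tables held 46 events, 23 skipped exons, 13 retained introns, 3 pairs of mutually exclusive exons, 4 alternative 3′ splice sites and 3 alternative 5′ splice sites, each with p = 1 and a false discovery rate of 1. Their tables of significant events held none. The p-value was the same at every event, also at the 27 with an absolute inclusion level difference of 1. The authors' comparison therefore cannot show that splicing was unchanged. Inclusion was higher on the first side of the comparison, which the name of the comparison makes likely to be ZCCHC7-OE, for 22 events and lower for 24. The median inclusion level difference in the authors' deposited tables was -0.0995, with a 95% order-statistic interval of -0.901 to 0.642. In 11 of the 46 events the 2 sides had counts only in different library positions, so unlike libraries may be compared there. Over the other 35, a set chosen after the data were seen, the median was 0.058.

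Members of the fixed gene groups had 3 skipped-exon events. In the authors' deposited table the exon of MCL1, an apoptosis regulator whose splicing SRSF1 is known to control, at chromosome 1, 150578244 to 150578491, had an inclusion level of 1 on the first side (3 inclusion and 0 skipping counts). On the second side the authors' deposited table gave 0.429 (4 inclusion and 2 skipping counts). For SRRM2, a spliceosome-associated SR-related protein, the authors' deposited table gave 0.331 from 7 and 5 counts, and 1 from 5 and 0. For MPHOSPH6, an exosome cofactor, the authors' deposited table gave 0 from 0 and 1 counts, and 0.185 from 2 and 3. No event was listed for ZCCHC7 or SRSF1.

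Depth limited the splicing comparison, since the events held a median of 4 junction counts and none had 20 in each library. Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within the event type, passed 1 of the 35 events that could be tested by library position at 0.05, and 1 of the 46 with the counts of a side's libraries added. It compares these libraries and not the genotypes.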

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

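Alternatives chosen after the data were seen were the median inclusion difference over events with counts in the same library position and Fisher's exact test with the counts of a side's libraries added. Restricting each list to peaks at or above its median fold left 115 wild type and 100 ZCCHC7-OE peaks, 76 wild type peaks shared, 39 only in wild type, 23 only in ZCCHC7-OE and 45 genes in both lists. Fewer peaks entered by construction. Requiring -log10 p of at least 10 left 72 and 66 peaks. At or above the median fold, the intergenic share was 28.7% in wild type and 26.0% in ZCCHC7-OE and the wild type 3′ UTR share 0%; the cause was not tested. Fisher's exact test called 1 mutually exclusive exon event by library position and 1 with added counts, against 0 in the authors' comparison, and the cause was not tested. The other 51 of the 64 alternative values, over other overlap rules, gene and feature assignment and splicing thresholds, stayed within 1.5 times the main count or within its interval. Ignoring strand changed nothing because the lists give none. The stricter splicing thresholds could only give 0, because the main counts were already 0, so their agreement carries no information. The median inclusion difference was -0.112 without length correction. It was 0.058, of opposite sign but within the wide interval, over the 35 events with counts in the same library position. No event had 20 junction counts in each library, so that filter gave no value, and the motif shares were not run for want of a genome sequence. No paired analysis was possible because each group has 1 library and the groups share only that replicate number. Depth limits both the splicing tables, with a median of 4 junction counts per event, and the peak lists, with at least 8 IP tags needed for a call at the genome-wide background.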

Other observations

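All tests in this part were chosen after the results they bear on were seen, and the depth tests of the wild type peaks were changed after their first outcome. In their first form, redraws from the observed tags alone excluded depth for the whole list, and a product of redraw chances excluded it for a set of genes with many coding peaks. That form was dropped because redraws from lower bounds lost far more peaks, and later forms that did not allow for how the genes had been picked were dropped too. Several coding peaks lay at one short stretch of the coding sequence and recurred at nearly the same codon in both genotypes; these genes were chosen after their values were seen. In NCL, the nucleolar protein nucleolin, both summits fell on codon 252 of 710, with 755 tags in wild type and 537 in ZCCHC7-OE. In HMGB2, a chromatin protein whose end is an acidic tail, the summits fell on codons 194 and 197 of 209, and the authors' q-value did not pass 0.05 in wild type. RANGAP1 had both summits on codon 383 of 587, UPF2 on codons 85 and 84 of 1272, EHMT2 on codon 372 of 1267, and BRD9 on codons 79 and 80 of 597. Coding sequence held the top summit of 78 wild type and 68 ZCCHC7-OE peaks in 37 genes each, 26 of them in both lists. Summits were spread along coding sequences, with a median position of 48.9% of the length in wild type and 43.7% in ZCCHC7-OE. Genes with peaks along most of their coding sequence weigh on these medians, such as CBL with 12 wild type and CAPN2 with 13 ZCCHC7-OE peaks. The medians therefore do not place the peaks at single short stretches.

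Intergenic peaks were concentrated in a few blocks. Of 82 wild type peaks that overlapped no annotated gene, 48 lay in 9 clusters of at least 3 peaks, and of 63 such ZCCHC7-OE peaks, 31 lay in 6 clusters. Clusters in both lists lay on chromosome 1 near 125178847 and 143185075, chromosome 4 near 49102479, chromosome 5 near 49601487, chromosome 16 near 46387837 and on the unplaced contig KI270438.1, mostly beside centromeres. No input tag lay near 64 of the 82 and 51 of the 63, and 47 and 49 overlapped a peak of the other list.

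The number of peaks in the wild type list alone may in part follow from depth. Redrawing each wild type peak from its tags at the ZCCHC7-OE depth lost 27.6 peaks on average and at most 45 in 10000 draws, against 87 observed. Redrawing with every peak at once at the lower bound of its tag count, an extreme allowance for peaks called on high draws, lost 61 to 96. The input background was scaled to the other depth and not redrawn. The lower depth and a change on ZCCHC7 overexpression therefore cannot be told apart for the list as a whole, because the answer turns on how far called peaks overstate their tags. In the other direction, 52 ZCCHC7-OE peaks were missing from the deeper wild type list, where redraws lost 2 to 16 from the observed tags and 27 to 52 from the lower bounds.

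None of the 12 wild type peaks on coding exons of CBL or the 5 of PLA2G4A recurred in ZCCHC7-OE. Redraws at that library's depth lost 0 to 7 CBL peaks from the observed tags and 2 to 11 from the lower bounds. No draw lost all 12, while some draws lost all 5 of PLA2G4A. Whether depth accounts for this is not settled, because the genes were picked for their loss and peaks of 1 gene may not be independent. Of the other wild type peaks in the same range of tags, 56.3% for CBL and 73.1% for PLA2G4A did not recur either. That share is not a measure of depth. Redraws of the 101 other peaks in the range of both genes lost 5 to 32 from the observed tags, while 56 did not recur. Fragments spread along the whole spliced mRNA are argued against in CBL, where peaks covered 80.9% of the coding sequence and 0% of the 8368 bp 3′ UTR. That reading takes the annotated 3′ UTR to be present in full in these cells, which was not checked. The 0% in PLA2G4A decides nothing because its 3′ UTR has only 473 bp. Copies of cloned coding sequence in the immunoprecipitate are a candidate explanation for the coverage of CBL, and cannot be told apart from other sources in PLA2G4A. Of exonic peak bases, 99.9% were coding in CBL and 100.0% in PLA2G4A. In genes with peaks in both lists the wild type and ZCCHC7-OE shares were 100.0% and 99.9% in CAPN2 and 100.0% and 93.9% in UBE2Q1. They were 92.3% and 90.9% in AVEN, and 91.1% and 78.3% in PSMB1. These shares leave out peak bases outside the exons. Of all wild type peak bases, 2199 of 2426 were coding in CBL but 1188 of 2882 in UBE2Q1. In CAPN2, 1686 of 3102 were coding in ZCCHC7-OE. A high coding share does not single out cloned sequence, because it was general. In the whole wild type list 73 peak midpoints lay in coding sequence, 1 in a 3′ UTR and 3 in 5′ UTRs. Whether SRSF1 binding to coding exons would give the coverage of CBL was not tested. The loss of that coverage on ZCCHC7 overexpression stays open, untested with 1 library per group.

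The peaks on HBB and at the 3′ end of GH1, genes of red blood cells and the pituitary, may also come from outside the cells' own mRNA. Spliced mRNA from blood cells is argued against by at least 391 intron bases in the HBB peak of either list, more than 1 fragment length, and no peak lay in HBA1, LYZ or PTPRC. Expression vector sequence is a candidate source, since globin introns and growth hormone polyadenylation regions are common vector parts. The 6 other exons of HBB and GH1 had no peak in either list, which vector parts would give. Without vector sequences to match, this cannot be told apart from RNA or DNA of the genes' own loci, and no biological explanation was tested.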
